A study of Pimephales promelas with 20 samples.

How the data were processed

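Total RNA from whole fathead minnow larvae, sampled 96 h after hatching, was made into small RNA libraries with the TruSeq small RNA kit, per the labels' protocols. The labels give 10 control and 10 EE2 libraries; they do not say how many larvae a library holds or whether exposure vessels were separate, so p-values measure the spread between these libraries. Per the labels' design text, the authors mapped reads to known fathead minnow miRNA sequences and to zebrafish (Danio rerio) piRNA sequences. The submitters' processing notes list bcl2fastq 2.19.1, Bowtie 1.2.3, limma 3.40.6 and edgeR 3.26.8, with no settings. The mismatches allowed, the treatment of reads that match several sequences, and the version of each reference are not given in the sources used here.

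The deposited tables hold raw read counts per reference sequence, with no normalization by the authors: whole numbers whose totals differ between libraries. There are 4 tables, marked F and R for each class. F and R were taken as reads on the forward and the reverse strand of the reference, which no label states. The miRNA tables hold 528 forward and 57 reverse entries in 20 libraries, and the piRNA tables hold 2025 forward and 584 reverse entries in 15 libraries; controls 5 and 8 and EE2 replicates 2, 3 and 10 have no piRNA column. Every forward miRNA entry has at least 100 reads over all libraries and every forward piRNA entry at least 73, so the tables are of entries above some minimum. Totals per library were 8.72 to 24.1 M counts (forward miRNA), 65152 to 211513 (reverse miRNA), 1.02 to 3.08 M counts (forward piRNA) and 56993 to 170677 (reverse piRNA). Read counts without molecular identifiers are not independent molecules, so intervals from counts cover counting error only.

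All 533 distinct miRNA identifiers are a shared prefix with a number; 0 matched a known miRNA name and 0 matched a symbol in the reference gene table. The 22 lists of miRNA families and tissue markers fixed before the data were examined could therefore not be matched, and their set tests were not run. No sequences or coordinates stand in the files used here, so no genome position is given. Of forward piRNA entries, 45.8% had another entry with a profile correlation over 0.98, against 3.79% of miRNA entries, and 10 had identical counts to another. Entries are therefore not independent of each other, and whether such entries share reads was not tested, since sequences were not used.

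Each table was tested for EE2 against control with edgeR 4.0.16 in R 4.3.3: filterByExpr with its minimum count of 10, TMM factors, robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Reverse tables used the library sizes and TMM factors of the forward table of their class. The filter left 478, 47, 1701 and 432 entries for forward miRNA, reverse miRNA, forward piRNA and reverse piRNA. Standard errors of log2 fold changes were taken from the F statistic. CPM are TMM-normalised with SD over libraries; reads per M, given for entries outside the filter and for single libraries, are relative to the unnormalised total of the forward table of their class. DESeq2 1.42.0 and, for the forward tables, limma 3.58.1 (voom) were alternatives. Library measures were compared by permutation of the difference of means (100000 resamples for the 20 miRNA libraries, exact over all splits for the 15 piRNA libraries; scipy 1.17.1), two-sided, over a family of 11. Group assignment used the nearest centroid on standardised log2 of reads per M plus 0.5, relative to the unnormalised table total and without TMM factors. It ran over 100 miRNA and 56 piRNA pairs of left-out libraries, with 100 random labelings.

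The fit was tested on simulated data, with counts drawn from the real means, library sizes and dispersions. Among 478 simulated miRNAs it called 64.1%, 82.8% and 96.8% of 1.5-, 2- and 4-fold changes, and 3.13% of its calls were false. Among 1701 simulated forward piRNA entries it called 7.46%, 32.8% and 86.4% of these, and 1.18% of its calls were false. Among 47 simulated reverse miRNA entries it called 100% of each size, with 2 of 21 calls false (9.52%), and among 432 reverse piRNA entries 5.17%, 32.8% and 91.2%, with 1.33% of calls false. The changes of 1.5-, 2- and 4-fold were put on 64, 64 and 63 of the 478 miRNAs and on 7, 6 and 6 of the 47 reverse miRNA entries. Among piRNA entries they were put on 67, 67 and 66 of 1701 forward and 58, 58 and 57 of 432 reverse. A larger share of changed entries eases the adjusted threshold. The rates therefore do not compare between tables and can overstate the power to find a few changes. With no simulated change it called 0 in each of the 4 tables. Simulated entries were drawn independently of each other, unlike the real ones, so these false rates need not hold for the real libraries. Some other splits of the real libraries gave calls with the same fit, as given under the flagged results. No 2 libraries of a group were alike within sampling noise: the smallest chi-square per degree of freedom was 204 (miRNA) and 40.9 (piRNA).

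Named entries were chosen by rules written before the data were examined: the smallest p and the most abundant entries per table, and for each list a member, which could not be matched. As the identifiers have no known names, the results give at most 2 miRNAs per direction from the 10 with the smallest p, besides the 5 most abundant; 3 others of the 10 appear only where a single library stood apart. The 4 entries that edgeR called in all 15 libraries without the filter but not with it, and the 1 more that DESeq2 called without it, were singled out after their values were seen. Alternatives were other scalings, filters and tools, added strands, a replicate block and leaving out each library.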

Results

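Small RNAs were measured in whole larvae of the fathead minnow (Pimephales promelas), a small cyprinid fish used in toxicity testing. Exposed larvae were kept from 48 to 96 h after hatching in water with 10 ng/L of 17α-ethinylestradiol (EE2), the synthetic estrogen of contraceptive pills, and control larvae were kept without it. There were 10 libraries in each group. Reads on miRNAs, which repress messenger RNAs, were deposited for all 20 libraries. Reads on piRNAs, which are known mainly for silencing transposons in the germ line, were deposited for 15 libraries (8 control and 7 EE2). The series title names the search for markers of this exposure as its purpose, so the comparison at each step was EE2 against control. Every miRNA carried a numbered identifier that the files used here do not pair with a known miRNA name. No miRNA family or tissue marker could therefore be followed, and entries are named by their identifiers.

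No difference between the groups was detected in the counts of each small RNA class or in their shares. The totals follow sequencing depth, so only the ratios and shares compare the classes within a library. Forward-strand miRNA counts per library were 14.8 ± 3.20 M in controls and 16.6 ± 4.22 M after EE2 (SD, n = 10 each; permutation test, two-sided, p = 0.291, adjusted p = 0.845). Forward-strand piRNA counts were 1.95 ± 0.533 M in 8 controls and 2.20 ± 0.710 M in 7 EE2 libraries (exact permutation test, p = 0.448, adjusted p = 0.845). For every 100 miRNA counts there were 12.8 ± 2.78 piRNA counts in controls and 13.1 ± 4.19 after EE2 (exact permutation test, p = 0.861, adjusted p = 0.861). Reverse-strand reads were 0.770% ± 0.0819 of miRNA counts in controls and 0.731% ± 0.0712 after EE2 (permutation test, p = 0.263, adjusted p = 0.845). They were a larger part of piRNA counts, at 5.52% ± 0.861 in controls and 5.24% ± 0.985 after EE2 (exact permutation test, p = 0.560, adjusted p = 0.845). None of the 11 library measures compared in this family passed the adjusted threshold.

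**Figure D1:**
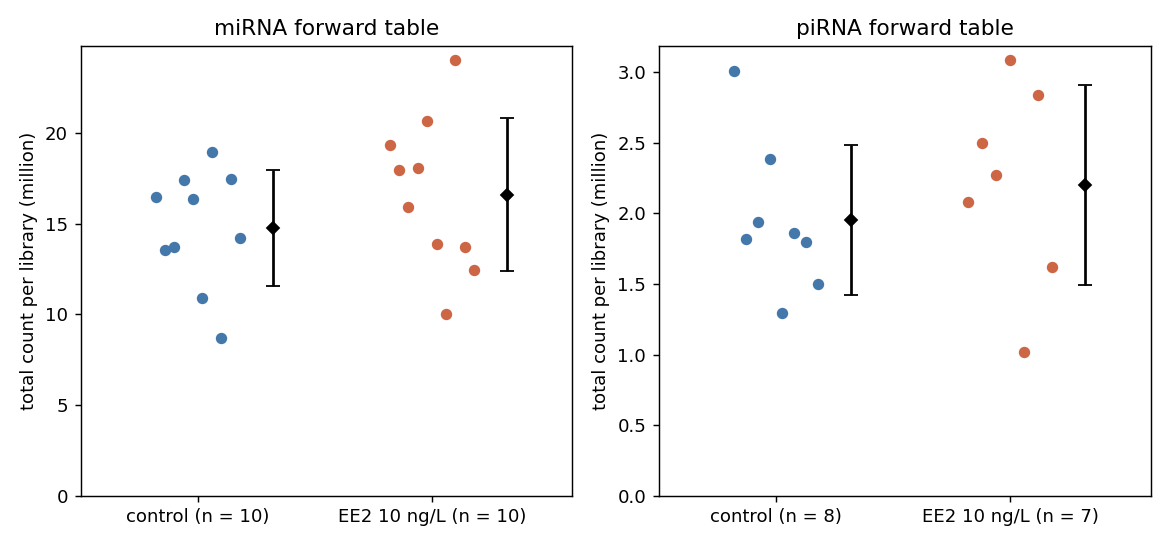
Total count per library in M counts (vertical axis) in the forward-strand miRNA table and the forward-strand piRNA table, for control (blue) and EE2 (orange) libraries; each point is a library, and black diamonds with bars are the mean ± SD. The groups overlap in both tables, from 8.72 to 24.1 M miRNA counts and from 1.02 to 3.08 M piRNA counts.

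The miRNA pool of the larvae was dominated by a few sequences whose shares were close in both groups. novelMiR_21068 took 18.8% ± 2.51 of miRNA counts in controls and 18.2% ± 1.73 after EE2 (SD, n = 10 each). novelMiR_45908 took 13.6% ± 1.48 and 13.3% ± 1.65, novelMiR_27736 took 8.14% ± 1.03 and 8.48% ± 1.05, and novelMiR_25637 took 6.32% ± 0.331 and 6.07% ± 0.271. The fifth most abundant, novelMiR_13707, took 4.06% ± 0.460 and 4.36% ± 0.281. Its normalised level was above the control median in 10 of 10 EE2 libraries, with a log2 fold change of 0.20 ± 0.08 (SE), and it did not pass the test (edgeR quasi-likelihood, p = 0.0164, adjusted p = 0.721). The 10 most abundant miRNAs held 67.7% ± 1.47 of counts in controls and 67.3% ± 2.01 after EE2.

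No miRNA changed with EE2 at an adjusted p of 0.05. Of 478 miRNAs tested with edgeR's quasi-likelihood test, 0 passed, DESeq2 and limma voom also called 0, and 24 had an unadjusted p under 0.05 where 23.9 are expected by chance. Of those 24, 13 were higher and 11 lower after EE2, and scaling by library size alone gave 1 higher and 33 lower. Leaving out 1 library moved the number of 24 to between 14 (without control 1 or control 10) and 51 (without EE2 replicate 5), and it was 42 without control 6 and 15 without EE2 replicate 7, with 0 passing each time. The smallest p belonged to novelMiR_8405, at 1.34 ± 0.881 CPM in controls and 0.717 ± 0.180 CPM after EE2, a log2 fold change of -0.90 ± 0.29 (SE; adjusted p = 0.721). novelMiR_34601 did not pass either, at 1.51 ± 0.527 CPM in controls and 1.06 ± 0.175 CPM after EE2. In the other direction, novelMiR_1551 was 0.263 ± 0.342 CPM in controls and 0.861 ± 0.471 CPM after EE2, and the more abundant novelMiR_31828 was 900.3 ± 139 CPM and 1079 ± 154 CPM. For 393 of the 478 miRNAs (82.2%) the 95% interval of the fold change lay within a 2-fold difference either way, and for 234 it lay within a 1.5-fold difference. In simulated libraries of the same size and spread, the test called 64.1% of 1.5-fold changes and 82.8% of 2-fold changes. The simulation changed 64 of the 478 miRNAs by each of these folds and 63 by 4-fold. Changes in that many miRNAs ease the adjusted threshold, so these rates do not give the power to find a few changed miRNAs.

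**Figure D2:**
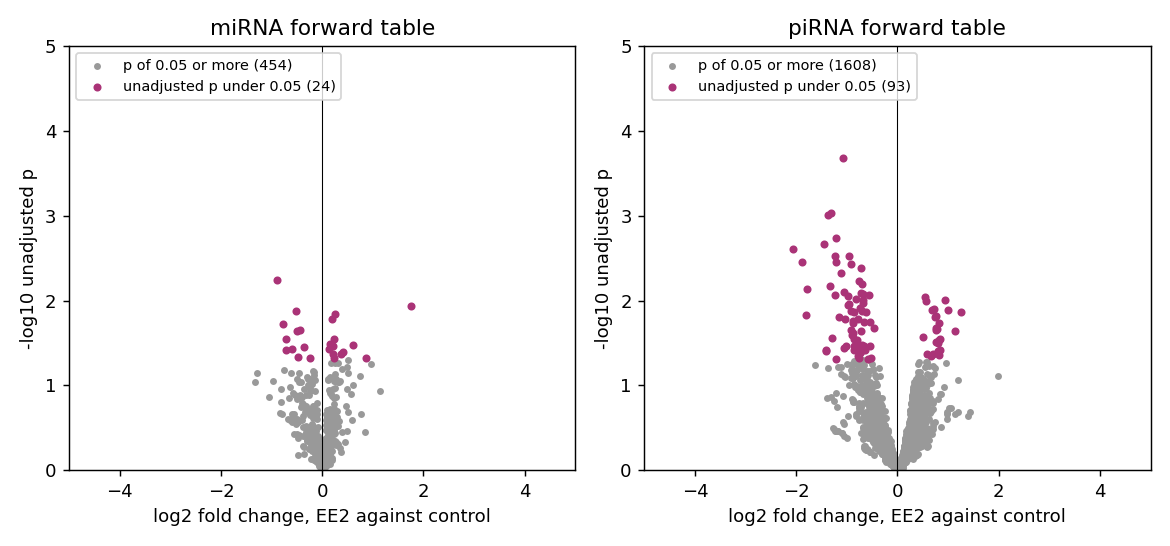
Log2 fold change of EE2 against control (horizontal axis) and -log10 of the unadjusted p from edgeR's quasi-likelihood test (vertical axis) for each tested entry of the forward-strand miRNA and piRNA tables. Coloured points have an unadjusted p under 0.05 (24 of 478 miRNAs and 93 of 1701 piRNA entries); none passed at an adjusted p of 0.05.

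piRNA reads, counted on zebrafish piRNA sequences, were spread over more entries and varied more between libraries (biological coefficient of variation 0.553, against 0.394 for miRNAs). The most abundant forward-strand entry, piR-dre-4794, took 8.90% ± 4.46 of counts in controls (n = 8) and 8.48% ± 3.91 after EE2 (n = 7). piR-dre-679748 took 5.55% ± 2.12 and 5.89% ± 3.20, and piR-dre-5462 took 5.05% ± 2.80 and 4.85% ± 2.31. After the filter on low counts, 0 of 1701 entries passed at an adjusted p of 0.05 with edgeR's quasi-likelihood test and 93 had an unadjusted p under 0.05, against 85.1 expected. Of these 93, 68 were lower and 25 higher after EE2, and scaling by library size alone gave 162 lower and 6 higher, with the share of all tested entries lower after EE2 moving from 45.7% to 66.0%. Leaving out 1 library gave from 71 (without EE2 replicate 9) to 230 (without EE2 replicate 6), with 148 without control 7. The smallest p belonged to piR-dre-36083, at 88.2 ± 15.8 CPM in controls and 41.7 ± 12.5 CPM after EE2, below the control median in all 7 EE2 libraries (log2 fold change -1.08 ± 0.23 SE, adjusted p = 0.355). piR-dre-1180 was 148 ± 73.6 CPM in controls and 60.1 ± 15.7 CPM after EE2 (log2 fold change -1.30 ± 0.33 SE, adjusted p = 0.557). DESeq2 on the same entries called 3, all lower after EE2 and including these 2, with adjusted p = 0.00120 for piR-dre-36083 and 0.0400 for piR-dre-1180, and limma voom called 0 (adjusted p = 0.201 and 0.713). Over all alternatives the adjusted p ran from 0.00109 to 0.999 for piR-dre-36083 and from 0.0400 to 0.999 for piR-dre-1180. The highest-ranked entries in the other direction were piR-dre-25956, at 12488 ± 2738 CPM in controls and 18283 ± 3988 CPM after EE2, and piR-dre-81975, at 1397 ± 363.4 CPM and 2672 ± 1714 CPM; neither passed (adjusted p = 0.586 for both). The 95% interval lay within a 2-fold difference for 816 of 1701 entries (48.0%), and in simulated libraries the test called 32.8% of 2-fold and 86.4% of 4-fold changes, so smaller differences were mostly not detectable at this depth and spread.

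A few piRNA entries were nearly absent from one group and were removed by the filter, which asked for enough reads in as many libraries as the smaller group holds. Without the filter, edgeR's quasi-likelihood test called 2 forward-strand entries, both higher after EE2. piR-dre-943955 had 0 to 4 reads in each of the 8 control libraries, 11 in all, and 108 to 228 reads in 6 of the 7 EE2 libraries. EE2 replicate 1 had 2 reads, as many as a control. Its level was 0.722 ± 0.746 reads per M forward-strand piRNA reads in controls and 60.6 ± 43.1 after EE2 (log2 fold change 6.55 ± 0.85 SE, adjusted p = 0.00150), and the pooled rate was 75.4 times higher after EE2 (95% interval 41.9 to 152, counting error only). piR-dre-195477 had 1 read in all controls together, 5 to 52 reads in the same 6 EE2 libraries and 1 read in EE2 replicate 1 (log2 fold change 6.36 ± 0.88 SE, edgeR adjusted p = 0.00150). Its pooled rate ratio was 131 (95% interval 23.05 to 5203, counting error only). Without control 10, with 0 reads in the other controls, its rate was at least 39.4 times higher, with 3 counts over the group as the floor. In fits chosen after seeing the data, DESeq2 without the filter also called both, at adjusted p = 3.06e-13 and 3.70e-07, while limma voom called neither, at adjusted p = 0.794 and 0.414; these are the ends of the range over all alternatives of each entry. DESeq2 without the filter called 1 more entry that was higher after EE2, piR-dre-5390 (log2 fold change 4.42 ± 1.00 SE, adjusted p = 0.00496), which edgeR did not call with or without the filter. Leaving out EE2 replicate 1 while keeping the filter also gave 1 call, piR-dre-943955. Leaving out control replicate 10, the control that held the read of piR-dre-195477, ended that entry's call in the unfiltered edgeR fit (adjusted p = 0.112). The remaining controls then held 0 reads of it, so the lost call does not show that the difference came from control 10.

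**Figure D3:**
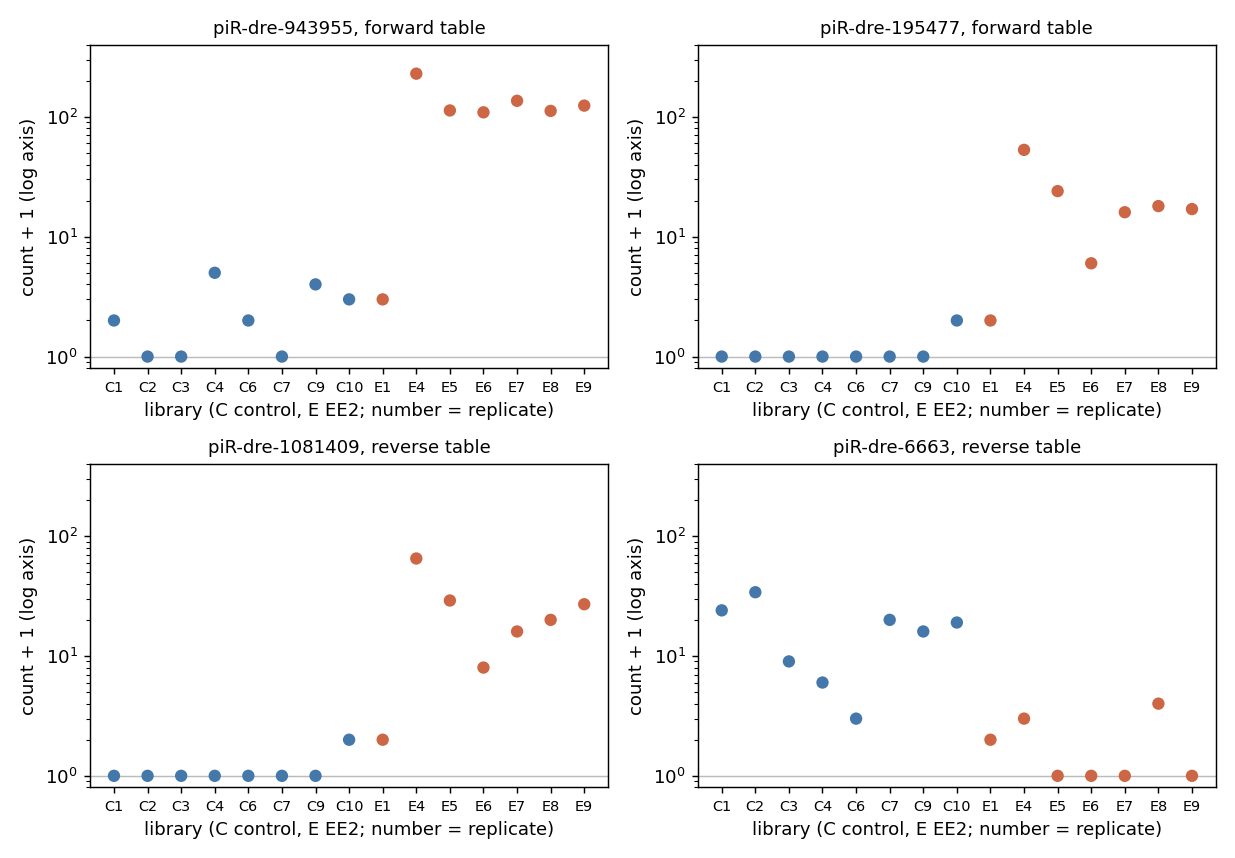
Read count plus 1 (vertical log axis) of the 4 piRNA entries that edgeR called in all 15 libraries without the filter on low counts but not with it, in each of the 8 control (C, blue) and 7 EE2 (E, orange) libraries, numbered by replicate (horizontal axis). The 3 entries that were higher after EE2 are near 0 in controls and in EE2 replicate 1 and reach up to 228 reads in the other EE2 libraries; piR-dre-6663 has 2 to 33 reads in controls and at most 3 after EE2.

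Reads on the strand opposite to the reference sequences were fewer and spread over fewer entries. Of 47 reverse-strand miRNA entries tested, 0 passed with edgeR's quasi-likelihood test and with DESeq2, and 2 had an unadjusted p under 0.05 with each (2.35 expected; 1 to 4 with 1 library left out, 4 without EE2 replicate 5). These were novelMiR_19525, at 2.18 ± 0.790 CPM in controls and 1.42 ± 0.542 CPM after EE2 (adjusted p = 0.564), and novelMiR_6822, at 1.62 ± 0.680 and 1.10 ± 0.343 CPM (adjusted p = 0.803). The reverse-strand miRNA reads fell mostly on novelMiR_27041, with 48.3% ± 3.04 of them in controls and 48.2% ± 2.59 after EE2, novelMiR_21576, with 30.5% ± 3.11 and 29.7% ± 3.23, and novelMiR_1998, with 8.67% ± 1.96 and 9.13% ± 2.02. Of 432 reverse-strand piRNA entries, 0 passed with either tool and 14 had an unadjusted p under 0.05 with edgeR (21.6 expected, 23 with DESeq2; 9 without EE2 replicate 7 to 34 without EE2 replicate 6, 28 without control 7, 27 without EE2 replicate 5 and 23 without control 9). The first of them was piR-dre-66662, at 139 ± 33.0 CPM in controls and 76.9 ± 28.2 CPM after EE2 (adjusted p = 0.761), followed by piR-dre-47571, at 11.5 ± 6.54 and 4.25 ± 2.59 CPM (adjusted p = 0.761). The most abundant were piR-dre-788364 (32.4% ± 7.14 of reverse-strand piRNA counts in controls, 31.4% ± 5.45 after EE2), piR-dre-1242964 (13.1% ± 3.08 and 14.4% ± 3.87) and piR-dre-1075393 (4.02% ± 0.919 and 4.498% ± 1.44). Without the filter edgeR called 2 entries, and so did DESeq2, a fit added after seeing the data. piR-dre-1081409 had 1 read in all controls, 7 to 64 in 6 EE2 libraries and 1 in EE2 replicate 1 (log2 fold change 6.66 ± 0.91 SE, edgeR adjusted p = 0.000698); without control 10, which held that control read, its rate was at least 48.8 times higher after EE2 against the same floor. piR-dre-6663 had 123 reads in controls and 6 after EE2, and had a lower rate than every control in 7 of 7 EE2 libraries (log2 fold change -4.08 ± 0.76 SE, edgeR adjusted p = 0.0147). Control 6 had only 2 reads (1.54 per M) and EE2 replicate 8 had 3 (1.06 per M), so counting error alone could change their order. The pooled rate was 20.2 times lower after EE2 (95% interval 9.03 to 56.2, counting error only). Without EE2 replicate 8, which held 3 of the 6 reads, the pooled rate was 33.0 times lower (95% interval 11.04 to 162, counting error only). limma voom without the filter, also added later, called neither (adjusted p = 0.395 for both). The adjusted p over all alternatives ran from 8.62e-08 to 0.395 for piR-dre-1081409 and from 0.000158 to 0.999 for piR-dre-6663.

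Because the series was made to look for markers, it was also asked whether the profiles assign a library to its group. With 1 control and 1 EE2 library left out at a time and 10 entries picked in the rest, 53% of the left-out miRNA libraries were assigned to their own group, and 44 of 100 random labelings did as well (permutation p = 0.446). For the filtered piRNA entries 67.0% were assigned correctly, and 16 of 100 random labelings did as well (permutation p = 0.168).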

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

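The tests weighing explanations in this part, and the splits of the libraries, were all written down after the values had been seen. Of 98 groups of libraries compared, 12 held a library set apart from the others by more than Dixon's 95% value. Chance would give about 4.9 for entries chosen beforehand. But 7 of the 12 belong to entries picked by their p or by how their levels differed between these libraries. Of these, 2 are a single read against counts of 0, so the numbers are not comparable.

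Among them were the entries nearly absent from 1 group: on the log2 scale of reads per M plus 0.5, piR-dre-943955 was 0.55 in EE2 replicate 1 and at least 5.15 in the other EE2 libraries, and piR-dre-195477 and piR-dre-1081409 were 0.22 in control 10, from a single read each, and -1 in the other controls. Shallow control libraries do not account for the contrast: at the EE2 rate the 8 controls would hold 830 reads of piR-dre-943955, and they held 11. Most reads of piR-dre-943955 cannot be those of piR-dre-195477, as the EE2 libraries held 819 of the first and 129 of the second. Whether the reads of piR-dre-195477 are also counted on piR-dre-943955 stays open. The ratio of the 2 entries ran from 4.38 to 21.6 over 6 EE2 libraries (chi-square p = 0.00352, counting error only). Without EE2 replicate 6 it reached only 9 and p was 0.0965. For piR-dre-195477 and the reverse-strand piR-dre-1081409 no departure from 1 ratio was found (1 to 1.63, chi-square p = 0.943, counting error only). Their counts were as low as 5 and 7 reads, in EE2 replicate 6. These may be the same reads on complementary entries, but separate reads that vary together could keep 1 ratio too, so this also stays open. Whether EE2 replicate 1 was a library of unexposed material could not be decided. It had 1 read of piR-dre-6663, a rate of 0.481 per M against 1.54 in the lowest control. But 1 or fewer reads at the rate of the lowest control has a Poisson probability of 0.170. piR-dre-6663 was also singled out for its low rates in the EE2 libraries, replicate 1 among them, so it is no independent guide. An effect of EE2 stays open as a hypothesis, as does an unrecorded difference in library preparation between the groups.

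The other libraries set apart are given as values. EE2 replicate 6 had 22.2 piRNA counts per 100 miRNA counts, the next EE2 library 13.8. Control 6 had 1955 forward piRNA entries with a read, the next control 1997. On the same log2 scale, novelMiR_17133 was -0.39 in control 7 and at least 1.22 in the other controls. novelMiR_40568 was 3.65 in EE2 replicate 3 and at least 4.35 in the other EE2 libraries. EE2 replicate 5 was highest for novelMiR_35457, at 5.76 against 5.08, and for novelMiR_24836, at 12.06 against 10.89. novelMiR_27736 was 15.88 in EE2 replicate 7 and at least 16.21 in the others. In the reverse tables, novelMiR_1998 was 9.83 in control 6 against 9.48 in the next control, and piR-dre-1075393 was 12.17 in control 9 against 11.29.

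Other ways of splitting the same libraries, 100 per table with the real one included, gave as many entries at an unadjusted p under 0.05 in 40 splits for forward miRNA (real 24, highest other 130), 73 for reverse miRNA (real 2, highest other 8), 40 for forward piRNA (real 93, highest other 545) and 82 for reverse piRNA (real 14, highest other 134), so chance is not excluded for these counts. Without the filter, 3 of 100 splits gave as many calls in the forward piRNA table (real 2, highest other 2) and 3 of 100 in the reverse piRNA table (real 2, highest other 69). Each share is under 0.05 taken alone but not after Benjamini-Hochberg adjustment over the 6 counts put to this test (0.09 for each). Only 100 splits were drawn, so a share of 3 is imprecise, and the calls were singled out after their values were seen. The 2 tables may also share reads, so chance is not excluded here either. With the filter, where the real split gave 0 calls in each table, some other splits gave calls. There were 5 such splits for forward miRNA, 7 for reverse miRNA, 4 for forward piRNA and 5 for reverse piRNA. The most calls in 1 split were 68, 2, 49 and 21. The splits that called 69 without the filter, or put 545 entries under 0.05, may reflect a structure of the libraries other than exposure or entries that vary together. Which libraries they part was not tested.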

How the results depend on the processing

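Alternatives added after seeing the data are named as added later. The miRNA counts of calls, forward and reverse, stayed at 0 under all alternatives run, including every left-out library. The forward piRNA count moved from 0 to 1 with a minimum mean CPM of 10 in place of the filter, to 2 without a filter and to 3 with DESeq2; DESeq2 without a filter, added later, gave 6. These differences come from which entries were tested or from the tool; the cause was not tested further. Leaving out single libraries gave 0 to 1, the 1 without EE2 replicate 1. The reverse piRNA count moved from 0 to 2 without a filter, with edgeR and, added later, with DESeq2. Other scalings, voom and added strands, run on the forward table, left its count at 0, as the reverse table's own library sizes did for the reverse count; collapsing near-identical entries, or leaving out control 2, control 7 and EE2 replicate 5 together, both added later, left both piRNA counts at 0. With a replicate block all 4 counts were 0; in the unfiltered fit, added later, the block kept piR-dre-943955 (adjusted p = 0.0173) and piR-dre-1081409 (0.0271) and ended the calls of piR-dre-195477 (0.403) and piR-dre-6663 (0.999), but the numbers were not found to pair the libraries: deviations of same-numbered libraries from their group means correlated over 0.1 in 2 of 10 pairs for miRNA and 3 of 5 for piRNA, and 0 correlated best with their own number. Of 620 fold changes of 22 named entries recomputed under alternatives, 609 kept their direction and side of the threshold, 7 were no longer past it, 4 were newly past it and 0 reversed. The 7 losses were all among the entries called without the filter, the only named entries past the threshold to begin with. Most of the 620 values came from leaving out 1 library, which leaves little room for change, so the tally is weak evidence of stability. Scaling by library size alone shifted the median log2 fold change by -0.10 for miRNA and -0.24 for forward piRNA, and the share of entries lower after EE2 from 47.5% to 69.0% and from 45.7% to 66.0%; entries at an unadjusted p under 0.05 then numbered 34 and 168. Library sizes summed over tables used the miRNA tables alone for the 5 libraries without piRNA columns. Among library measures, none of which passed any test, signs turned with medians for the reverse miRNA total (-0.00202 M), piRNA per 100 miRNA counts (-0.897), reverse share of piRNA (0.186 percentage points) and piRNA entries detected (1). Signs turned with the paired sign-flip for the forward piRNA total (-0.00977 M), reverse piRNA total (-0.0132 M) and top-10 share of piRNA (-0.699 percentage points); the cause was not tested. With 20 entries per fold, 65.0% of miRNA libraries were assigned to their group. The planned set tests of miRNA lists (camera, fry and their alternatives) were not run, for want of names.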

Other observations

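The tests in this part were chosen after the values had been seen. Libraries of 1 group differed far more from each other in some small RNAs than the groups differed. novelMiR_18155 was the most variable miRNA. It was at 66.3 or more reads per M miRNA reads in 11 libraries (6 control and 5 EE2) and at 3.04 or fewer in the other 9 (4 control and 5 EE2), a 21.8-fold gap with no library inside it. In controls it ranged from 0.632 to 223.1 and after EE2 from 0.481 to 166.

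A second contrast ran through many entries. Of 56 forward piRNA entries whose log2 level had an SD over 2 between libraries, 34 kept rank with piR-dre-644638 (Spearman rho over 0.8). piR-dre-644638 is the most abundant of the 56 and is itself counted among the 34, which together held 0.110% of piRNA counts. Near-identical entries were not collapsed here, so the 34 need not be separate sequences. piR-dre-644638 was 1125 reads per M in control 2, 837 in control 7 and 597 in EE2 replicate 5, between 92.1 and 278 in controls 1 and 10 and EE2 replicates 6 and 8, and at most 17.3 in the other 8 libraries. novelMiR_24836, chosen as the most abundant miRNA that kept rank with it, was 4292 reads per M in control 2, 3905 in control 7, 4255 in EE2 replicate 5, 3754 in control 1 and 3378 in control 10, but 1824 in EE2 replicate 6 and 1893 in EE2 replicate 8, closer to the median of 1522 over 20 libraries. Exposure does not account for the whole split, as 4 controls and 3 EE2 libraries lay above the gap and 4 of each below it (exact permutation p = 0.471), nor does depth (Spearman rho with the total count 0.05, permutation p = 0.861). The piRNA reference alone does not account for it either: 13 of 478 miRNAs had an absolute rho over 0.8 with piR-dre-644638, 12 positive, against a median of 0 in shuffled libraries (permutation p = 0.0004). A candidate explanation is a difference between the larvae of different libraries that the labels do not record, such as sex, genotype, stage or gut content. It was not tested, and the number of larvae per library is not given.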
